A study of Arabidopsis thaliana with 18 samples.

How the data were processed

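Small RNA was sequenced from rosette leaves of Arabidopsis thaliana Col-0. Plants 5 to 6 weeks old were left untreated, mock treated or sprayed with spores of the fungus Alternaria brassicicola (1000000 spores per ml with 0.01% Silwet, a wetting agent). Leaves of Alternaria-treated plants were harvested on day 3. For mock plants no harvest day or Silwet concentration is recorded, and for untreated plants no harvest day. Each of these 3 treatments gave 3 biological replicates. Small RNA was sequenced from total RNA and from RNA bound to the protein ARGONAUTE1 (AGO1), recovered by immunoprecipitation, which makes 18 libraries in 6 groups of 3. Total and AGO1 libraries were prepared by different protocols.

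The authors trimmed the reads with cutadapt after quality control with FastQC, and profiled them against known plant miRNAs with miRProf, with no mismatch allowed and with all organisms and variants of a miRNA combined into 1 family. Per the file headers, reads had to match the genome, build TAIR10, and pass a minimum abundance. The deposited table gives whole read numbers for each mature sequence and sequencing run, which stand among family-name lines without numbers, so its unit was recorded as other than a plain count table. The lowest value listed in any run is 15, so a sequence listed at 0 can have had up to 14 reads per run and 28 per library. The table holds 101 families with 498 entries for 476 distinct sequences, of which 22 stand in more than 1 family. The authors also deposited 15 tables of comparisons made with DESeq (version 1.2, with DESeq2 named beside it in the processing notes), of which the 9 that match a comparison below were read. In these, the authors give group means of normalized counts as a signal, a log2 ratio of these means, and a p-value with its adjusted p-value for each family. Their columns were compared with the values fitted here and entered no test.

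The 2 sequencing runs of a library were summed, since they are repeats of 1 library and not replicates. Family totals were scaled to counts per 1000000 (CPM) of the library's miRNA reads with trimmed mean of M-values factors (TMM), trimming 0.3 of the ratios and 0.05 of the abundances. Families were tested when enough libraries held 10 counts at the median depth and the total over libraries was 15 or more. Tests used limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trend of the spread on abundance, robust moderation and Benjamini-Hochberg adjustment over all families tested, at an adjusted p of 0.05. Adjusted p-values below are from this test. The count model chosen for these comparisons before the data were examined was replaced by limma, the fallback written with it, because the table could not be recorded as plain counts. Other data handling used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

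Total and AGO1 libraries were fitted apart (9 libraries each) for the comparisons of Alternaria with mock, Alternaria with untreated and mock with untreated. All 18 libraries were fitted together for AGO1-bound against total small RNA, as the mean of 3 treatments and for each treatment, and for the interaction that asks whether a change with Alternaria differed between AGO1-bound and total libraries. These 11 comparisons, the filters, the family lists and the rule for naming families were chosen before the data were examined. By that rule, up to 10 families each way past the threshold (up to 5 in secondary comparisons, all where 20 or fewer passed) with a mean of at least 10 reads in a group, the 5 most abundant families of each library type and up to 4 members of each list with the smallest p were named. The 11 lists held families by known role: defence, triggers of phased secondary small interfering RNAs, auxin, copper, phosphate, sulfate and nitrogen, development, silencing machinery, secondary metabolism, partners of other ARGONAUTE proteins, and families described from other organs as a check on tissue. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted within each of 7 comparisons. The families that passed the test in total libraries were tested as sets in the AGO1 libraries with fry, adjusted over the 2 sets. Sequences that began with U, and sequences 21 nt long, were compared with the others by a two-sided permutation test with 100000 resamples. The share of genome-matched reads taken by miRNAs was compared between groups by exact two-sided permutation tests.

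Every sequence was matched exactly to the 5 nuclear chromosomes and both organelle genomes of the RefSeq copy of the Arabidopsis assembly. For 461 of the 476 sequences the number of matches equalled the number in the deposited table, so the copy was treated as the build the authors named. Of the 101 families, 8 had no sequence within an annotated MIR transcript. The method was tested on simulated libraries in which 20 families changed by 2-fold or 4-fold. It recovered 86.0% of 2-fold and 99.3% of 4-fold changes between Alternaria and mock in total libraries, and 77.0% and 100% in AGO1 libraries, with 2.55% to 5.21% of calls false. The changed families were drawn from those with a mean of at least 100 reads, and all families had the same spread. Recovery was counted among tested families, and the listing minimum was applied to family totals. The rates therefore do not describe scarcer or more variable families. For AGO1-bound against total libraries, 58.7% of calls were false at 2-fold and 57.7% at 4-fold, because the listing minimum hides more families in the shallower total libraries. With all libraries thinned to the smallest miRNA total, 0.754 times 1000000 reads, 5.57% and 12.7% were false, so that comparison is given with and without thinning.

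Replicate numbers did not pair the samples on average: the residuals of libraries with the same number had a mean correlation of -0.00728 over 18 pairs of treatments, so no block was used in the tests, and results with the number as a block are given beside them. Alternatives planned before the data were examined were other scalings, other filters on low counts, merged identical families, the replicate number as a block, all 18 libraries in 1 fit, and each replicate left out in turn. A second count test, also planned, was not run, because the table could not be recorded as plain counts. Alternatives chosen after seeing the data were limma-voom, added pseudocounts of 10 and 25 CPM, each sequencing run alone, zeros of a family set to the largest hidden count of 1 sequence, removal of the families without a MIR transcript, scaling to genome-matched reads, untreated total replicate 3 left out of the comparison of Alternaria with mock in total libraries, replicates left out for the lists and for base and length, and thinning. Figures were drawn with matplotlib 3.10.9. Tables that compare a total library of one treatment with an AGO1 library of another were not used, since 2 things differ between them.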

Results

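The data were read numbers of 101 miRNA families in 18 small RNA libraries of rosette leaves: total small RNA and AGO1-bound small RNA, each from untreated, mock-treated and Alternaria-treated plants, with 3 biological replicates per group. In units of 1000000 miRNA reads, total libraries held 1.76 on average (range 0.754 to 3.03) and AGO1 libraries 16.2 (range 10.8 to 20.3). By group and in the same unit, total libraries held 1.12 ± 0.613 (untreated), 1.87 ± 1.01 (mock) and 2.28 ± 0.671 (Alternaria; mean ± SD, n = 3), and AGO1 libraries 17.7 ± 3.13, 15.3 ± 2.81 and 15.6 ± 4.50 in the same order. A sequence listed at 0 in a library can hold up to 28 reads, so a family listed at 0 can hold that number for each of its sequences. The limits stated here cover counting only. Values are CPM of miRNA reads, given as mean ± SD with n = 3 per group, and log2 changes carry their standard error.

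The most abundant families of total libraries were miR166 (16.04% of the miRNA reads of 9 libraries pooled), miR168 (15.3%), miR390 (14.01%), miR159 (8.17%) and miR158 (7.84%). By mean CPM miR390 (150781) stood above miR168 (150287). In AGO1 libraries miR166, which targets HD-ZIP III transcription factors, took 59.4% of the pooled miRNA reads, followed by miR158 (18.6%), miR165 (7.48%), miR159 (5.84%) and miR156 (5.47%). The main sequence of miR166 matches 7 MIR loci, the first at chromosome 2, positions 19176241 to 19176261. The main sequences of miR156 and miR157 are shared, and 99.97% of miR165 reads are of sequences shared with miR166, so within each pair the families are not independent. The same holds for miR384 and miR394, which share all their reads, for miR170 and miR171, and for miR5139 and miR8155. Counts of families below include both members of such pairs.

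The comparison of Alternaria with mock in total small RNA asks which miRNAs differ with the fungus, if mock plants were otherwise handled alike. miR827, which is induced by phosphate starvation and targets the ubiquitin ligase NLA, rose from 594 ± 26.98 CPM in mock to 2988 ± 488 CPM after Alternaria (log2 change 2.32 ± 0.23, adjusted p = 8.08e-06). miR399, another phosphate-starvation miRNA, rose from 447 ± 104 to 803 ± 51.7 CPM (0.87 ± 0.24, adjusted p = 0.0445), and miR391, a relative of miR390, rose from 3324 ± 1105 to 6720 ± 524 CPM (1.07 ± 0.28, adjusted p = 0.0380). By strand, miR399 did not pass (3p 0.79, adjusted p = 0.127; 5p 0.50, adjusted p = 0.590), and miR391 passed in 3p (1.16, adjusted p = 0.0265) and not in 5p (0.76, adjusted p = 0.239). miR169 fell from 518 ± 83.2 to 206 ± 21.3 CPM (log2 change -1.32 ± 0.26, adjusted p = 0.00674), in its 3p strand. A sequence set named miR5368, which matches plastid 23S rRNA and no MIR locus, was listed at 35.6 ± 14.5 CPM in mock and at 0 in all 3 Alternaria libraries (adjusted p = 0.0307).

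These 5 families, 3 higher and 2 lower of 77 tested, were all that passed the limma test, and 13 had an unadjusted p under 0.05. With median-of-ratios factors, and with library totals alone, 1 was higher and 2 lower. With the replicate number as a block, only miR827 and miR169 passed (adjusted p = 0.0723 for each of the other 3). Limma-voom called 4 higher and 2 lower, including all 5. The authors' deposited table of this comparison has 3 families with an adjusted p under 0.05, miR827, miR163 and miR5368. The main sequence of miR827, TTAGATGACCATCAACAAACT, lies at chromosome 3, positions 22122811 to 22122831 (MIR827). That of miR399 lies at chromosome 1, positions 23345387 to 23345407 (MIR399b), that of miR391 at chromosome 5, positions 24293160 to 24293180 (MIR391), and that of miR169 at chromosome 3, positions 4805713 to 4805733 (MIR169f, 3p strand). miR163, which targets methyltransferase genes of secondary metabolism, was at 1901 ± 830 CPM in mock and 12867 ± 6314 CPM after Alternaria and did not pass the test (log2 2.74 ± 2.88, adjusted p = 0.598). The spread behind this test was set by 1 library: miR163 was listed at 0 in untreated total replicate 3, and in a fit without that library, chosen after seeing the data, its log2 change was 2.48 with an adjusted p of 0.00248. Without that library miR391 (log2 0.81, adjusted p = 0.108) and miR399 (0.61, adjusted p = 0.142) did not pass. The calls of miR827 and miR169 held without any 1 of the 7 libraries tried. Those of miR391, miR399 and miR5368 did not: miR391 passed without 1 of the 7 (mock replicate 1; highest adjusted p 0.174), miR399 without 1 (mock replicate 2; highest 0.248) and miR5368 without 2 (mock replicate 3 and untreated replicate 3; highest 0.114).

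Grouped by known role, 2 of 3 tested phosphate families rose (miR827 and miR399), and the third, miR2111, did not pass (log2 0.31, adjusted p = 0.645). The list passed camera at the preset correlation (median log2 0.87, adjusted p = 0.0200), with an adjusted p = 0.145 with an estimated correlation. With the replicate number as a block it did not pass (adjusted p = 0.0560). Adjusted over the list alone, the same 2 members were higher. In the sulfate and nitrogen list, too small for a set test, miR169 fell and 1 of 2 tested members did not pass. Of the other lists none passed. The defence list had 8 tested members, none past the test (median log2 0.52, adjusted p = 0.975), among them miR398 (-0.61), miR393 (0.68), miR863 (0.73) and miR472 (0.60). The trigger list had 7 (median 0.52, adjusted p = 0.975), the auxin list 5 (0.45, adjusted p = 0.975), the development list 10 (0.05, adjusted p = 0.975, with miR159 at 0.50, miR172 at 0.55 and miR164 at -0.54), the silencing list 4 (0.28, adjusted p = 0.807, with miR838 at 3.11) and the list of partners of other ARGONAUTE proteins 3 (0.01, mean -0.09, adjusted p = 0.807). The camera direction of the defence and trigger lists was down while their medians were positive. The copper list had 2 tested members, miR408 (0.67) and miR398 (-0.61), and adjusted over the list alone 1 was higher and 1 lower. Lists of other organs and secondary metabolism had 1 tested member each, miR846 (0.83) and miR163, which did not pass.

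**Figure D1:**
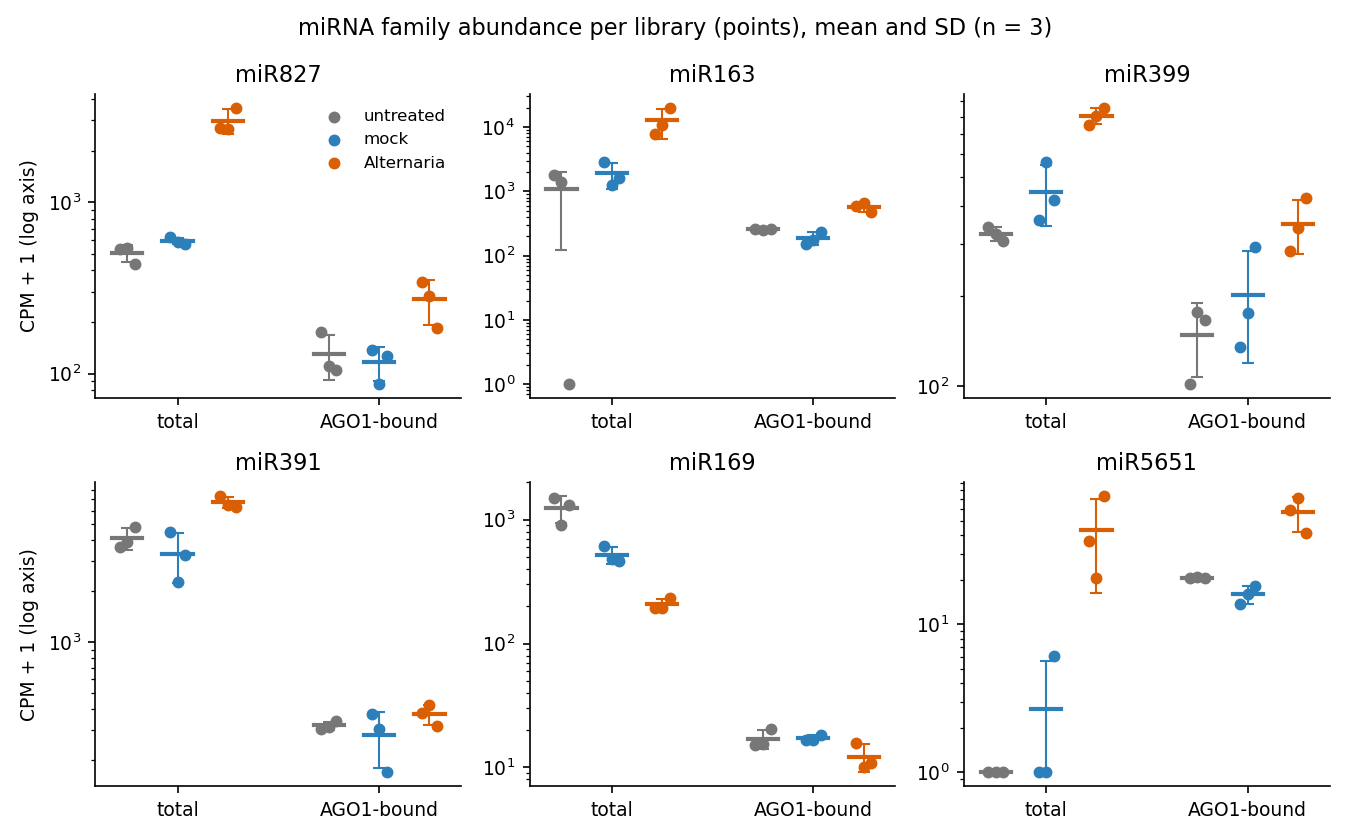
CPM + 1 on a log axis of 6 miRNA families in total and AGO1-bound libraries of untreated, mock and Alternaria plants. Points are libraries, lines are group means and error bars are SD (n = 3; a lower bar that would pass 0 ends at 0), and a family listed at 0 sits at 1. miR827 in total libraries was at 2988 CPM on average after Alternaria and at 594 CPM in mock.

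Alternaria and untreated leaves, compared in total small RNA, differ by the treatment itself as well as by the fungus. miR827 rose from 503 ± 58.7 to 2988 ± 488 CPM (log2 2.56 ± 0.23, adjusted p = 2.33e-06) and miR399 from 322 ± 16.8 to 803 ± 51.7 CPM (1.31 ± 0.24, adjusted p = 0.00136). By strand, miR399 passed in 5p (1.60, adjusted p = 0.00727) and not in 3p (0.67, adjusted p = 0.0745). miR2111, the remaining phosphate family tested, rose from 71.1 ± 18.2 to 176 ± 18.2 CPM (1.32 ± 0.38, adjusted p = 0.0191). In the fit by strand only its 3p strand was tested (1.01, adjusted p = 0.0562), so that value does not separate strands. miR169 fell from 1242 ± 309 to 206 ± 21.3 CPM (log2 -2.56 ± 0.26, adjusted p = 5.02e-06). miR393 rose from 239 ± 44.7 to 656 ± 277 CPM (1.36, adjusted p = 0.00951), in its 3p strand (1.34, adjusted p = 0.00937) and not in 5p (-0.55, adjusted p = 0.633). miR172 rose from 1967 ± 719 to 4217 ± 628 CPM (1.15, adjusted p = 0.00951), though neither strand passed alone (5p 1.07, adjusted p = 0.0562; 3p 0.45, adjusted p = 0.335). Fragments without a MIR locus were lower: miR4995 and miR5368 (plastid 23S rRNA) went from 340 ± 55.1 and 191 ± 217 CPM to a listing at 0, and miR6173 (plastid 16S rRNA) fell from 563 ± 178 to 83.8 ± 4.03 CPM (adjusted p = 0.00117).

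Limma called 12 of 77 families higher and 7 lower, limma-voom 12 and 10. The other families higher were miR846 (36.6 ± 13.4 to 178 ± 99.3 CPM, adjusted p = 0.00951), miR408 (log2 0.91, adjusted p = 0.0374, neither strand passing alone), miR866, miR5654, and miR400, miR5651 and miR838, which were listed at 0 in all untreated libraries. The other families lower were miR8175 (-3.99, adjusted p = 0.00891), of whose reads 41.9% also match tRNA, and miR8155 (-2.04) and miR5139 (-1.45), which have no MIR locus. All miR8155 reads are of a sequence that also makes up 67.2% of miR5139 reads, so these calls are not independent. All 3 phosphate members were higher as families and the list passed camera at the preset correlation (adjusted p = 0.0171) and with the replicate number as a block (adjusted p = 0.0451), with an adjusted p = 0.136 with an estimated correlation. The list was drawn by family and did not separate strands. By strand, miR399 passed in 5p alone, while 3p made up 100% of its listed reads in AGO1 libraries, and miR2111 was tested in 3p alone. No other list passed. With untreated total replicate 1 left out, no list passed, the phosphate list included. miR163 had a log2 of 6.44 with an adjusted p of 0.131, and 2.61 with an adjusted p of 0.00283 without untreated total replicate 3. miRNAs took a larger share of the genome-matched reads in treated leaves, 2.63 ± 0.114% in untreated, 8.54 ± 4.15% in mock and 9.56 ± 1.96% in Alternaria libraries (exact permutation p = 0.1 for either against untreated, the smallest value that 3 against 3 can give, and 0.7 for Alternaria against mock; adjusted 0.3, 0.3 and 0.9). Changes are therefore relative to the other miRNAs: the median log2 change of all families was 0.35 when scaled to miRNA reads and 2.13 when scaled to genome-matched reads, where 58 families passed as higher and 3 as lower and miR169 did not pass (-0.79, adjusted p = 0.182). The calls of miR827, miR169, miR399, miR4995, miR5368, miR6173, miR866 and miR8175 held without any 1 of the 6 libraries, and the other 11 did not (number of calls 10 without Alternaria replicate 3).

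Mock and untreated leaves, the control for the treatment itself, differed in 4 of 77 families of total small RNA when scaled to miRNA reads, all lower in mock. Some settings with that scaling also gave higher families: 4 higher and 4 lower without untreated total replicate 1, and 5 and 6 in the fit of all 18 libraries. When scaled to genome-matched reads, 47 families passed as higher in mock and 1 as lower (median log2 1.67), so the direction depends on the scaling. miR169 fell from 1242 ± 309 to 518 ± 83.2 CPM (log2 -1.24 ± 0.26, adjusted p = 0.0120). The other 3 have no MIR locus: miR6173 (-2.41, adjusted p = 0.0120), miR5139 (-1.63, adjusted p = 0.0251) and miR4995, listed at 0 in 2 of 3 mock libraries (340 ± 55.1 to 15.4 ± 26.8 CPM, adjusted p = 0.0154). Limma-voom called 3 lower, 14 families had an unadjusted p under 0.05, the median log2 was 0.21 and no list passed (phosphate, the lowest, adjusted p = 0.168). None of the 4 calls held without untreated total replicate 3 (miR169 -1.21, miR6173 -2.20, miR5139 -1.12). Of them 3 ended without untreated total replicate 2 or without mock total replicate 3, and 2 without mock total replicate 2. With genome-matched scaling miR169 had the opposite direction (log2 0.38, adjusted p = 0.550).

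**Figure D2:**
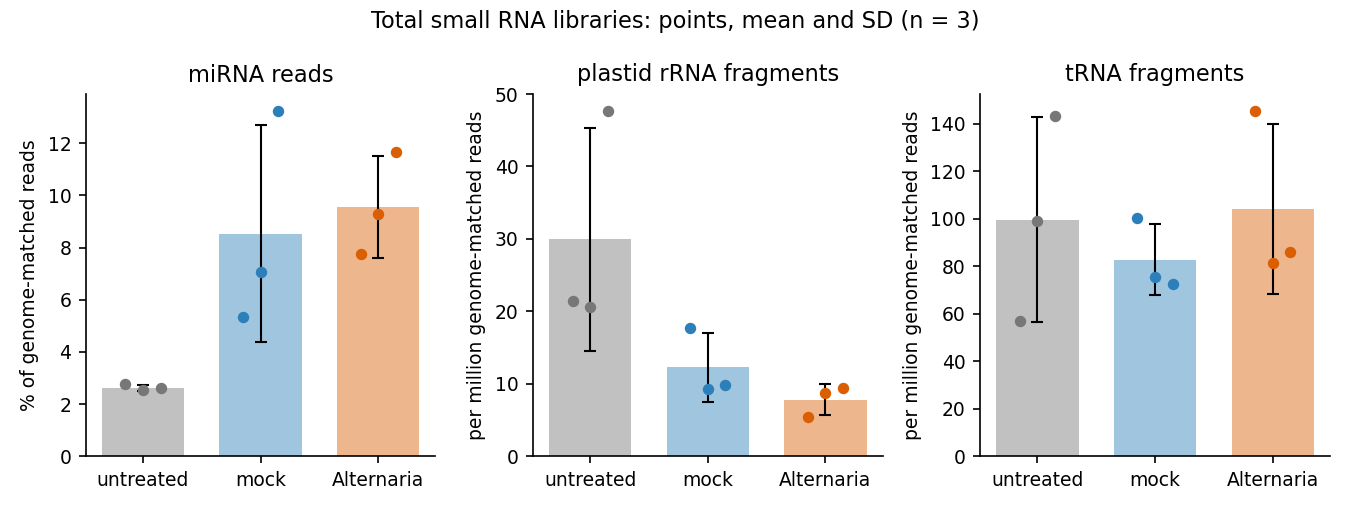
Total small RNA libraries by treatment: miRNA reads as percent of genome-matched reads, and plastid rRNA and tRNA fragments per 1000000 genome-matched reads. Points are libraries, bars are means and error bars are SD (n = 3). miRNA reads took 2.63% in untreated, 8.54% in mock and 9.56% in Alternaria libraries on average.

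The comparison of Alternaria with mock in AGO1-bound small RNA asks which miRNAs differ in the fraction loaded into the main slicing ARGONAUTE. 4 families rose and none fell. miR163 rose from 188 ± 43.6 to 571 ± 95.8 CPM (log2 1.61 ± 0.27, adjusted p = 9.72e-05) and miR5651 from 14.9 ± 2.17 to 56.1 ± 14.9 CPM (1.82 ± 0.28, adjusted p = 6.36e-05). miR827 rose from 116 ± 26.7 to 270 ± 79.3 CPM (1.19 ± 0.29, adjusted p = 0.00799) and miR846, which targets jacalin lectin genes, from 116 ± 35.5 to 218 ± 44.7 CPM (0.93 ± 0.26, adjusted p = 0.0322). By strand, miR163 and miR5651 passed, but miR827 (3p, adjusted p = 0.0756) and miR846 (3p, adjusted p = 0.113) did not. For miR163, miR5651 and miR827 a single strand was tested, so these values come from a refit and do not separate strands. With the replicate number as a block 6 families were higher, these 4 among them, and 1 was lower. The main sequence of miR163, TTGAAGAGGACTTGGAACTTCGAT, lies at chromosome 1, positions 24884359 to 24884382, that of miR5651 at chromosome 3, positions 17178489 to 17178509, and that of miR846 at chromosome 1, positions 22577662 to 22577682.

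Of 79 families 13 had an unadjusted p under 0.05, limma-voom called the same 4 and the median log2 was -0.00356. The families that were higher in total libraries, miR391, miR399 and miR827, were higher as a set in AGO1 libraries (mean log2 0.84, adjusted p = 9.15e-05 by fry of limma), while miR169, the lower family that could be tested, had a log2 of -0.52 and gave no firm result (adjusted p = 0.0433 by fry and 0.428 by the test of single families). It did not pass fry with the replicate number as a block or without 5 of the 6 libraries in turn. Its reads were 98.4% from the 3p strand in total libraries and 0% in AGO1 libraries, so its value in AGO1 is that of another strand than the one that fell. For a change of the higher set in either direction fry gave an adjusted p = 0.0604. Of the AGO1 reads of miR391, 0.0637% were from 3p, the strand that passed in total libraries. Its 5p strand did not pass in AGO1 libraries (log2 0.43, adjusted p = 0.512 by limma), so the set's value for miR391 is also that of another strand. In the copper list miR398, which targets copper superoxide dismutases, and miR408 had values of -0.79 (adjusted p = 0.0914) and -0.67 (adjusted p = 0.212); adjusted over the list alone both were lower, but the list did not pass camera (adjusted p = 0.0704). Adjusted over the list alone, both tested phosphate families, miR827 and miR399 (0.85, adjusted p = 0.107), were higher. miR846 was the 1 member of 3 higher in the list of other organs (adjusted p = 0.0704), and miR163 the 1 of 3 in that of secondary metabolism (adjusted p = 0.428). The other lists had no member past the test: defence (10 members, adjusted p = 0.330), triggers (7, 0.376), auxin (5, 0.466), development (10, 0.518), silencing (4, 0.757), partners of other ARGONAUTE proteins (3, 0.974), and sulfate and nitrogen (2, not tested). The calls of miR163 and miR5651 held without any 1 of the 6 libraries; that of miR827 ended without each of them (adjusted p 0.0741 to 0.140), and that of miR846 without mock replicate 1 (0.62), mock replicate 2 (0.84), Alternaria replicate 2 (0.74) or Alternaria replicate 3 (0.65). In a fit of all 18 libraries none of the 4 passed. The authors' table of this comparison lists 5 families, of which miR163, miR5651, miR827 and miR845 had an adjusted p under 0.05; miR845 did not pass here (log2 1.49, mock listed at 0, adjusted p = 0.221).

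Against untreated leaves, AGO1-bound miR5651 (log2 1.43, adjusted p = 0.00226), miR163 (1.15, adjusted p = 0.00670), miR399 (1.25, adjusted p = 0.00670), miR827 (1.05, adjusted p = 0.0170) and miR846 (0.90, adjusted p = 0.0283) rose after Alternaria, of which miR846 did not pass by strand (3p, adjusted p = 0.0552). miR164, which targets NAC factors, fell from 32.9 ± 8.43 to 13.2 ± 3.73 CPM (-1.26, adjusted p = 0.00670), and miR6478, which matches tRNA, rose from 13.2 ± 2.15 to 24.7 ± 3.77 CPM. These 6 higher and 1 lower of 79 compare with 6 and 3 by limma-voom, and the median log2 was -0.07. The number past the threshold was 14 without untreated AGO1 replicate 3, 3 and 1 without untreated replicates 1 and 2, and 0 and 2 without Alternaria AGO1 replicates 2 and 3. Between mock and untreated AGO1 libraries none of 79 families passed by limma or limma-voom, with 5 at an unadjusted p under 0.05 by either. The median was -0.17, and without untreated AGO1 replicate 3, 1 passed. No list passed in either comparison (lowest adjusted p = 0.188 for other organs and 0.312 for secondary metabolism).

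AGO1-bound against total small RNA asks which miRNAs are held by AGO1 relative to their share of all miRNA reads. As the mean of 3 treatments (9 libraries against 9), miR850 (log2 4.33 ± 0.16), miR398 (3.57 ± 0.15), miR166 (2.99), miR158 (2.49) and miR165 (2.27) were higher in AGO1. miR390, the partner of AGO7 (log2 -8.16 ± 0.13), miR172 (-7.83 ± 0.22), miR173, which initiates secondary small interfering RNAs (-5.41 ± 0.15), and miR168, which targets the AGO1 transcript itself (-5.01 ± 0.16), were lower, as was miR164 (-9.75 ± 0.19). These 10 families, of which miR165 and miR166 share sequences, had the same direction and passed under all 3 scalings to miRNA reads. miR827, which rose after Alternaria, was lower in AGO1 than in total (-1.48), as was miR2111, listed at 0 in AGO1 libraries.

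Limma called 39 of 95 families higher and 42 lower (82 at an unadjusted p under 0.05; limma-voom 34 and 43). The median log2 of all families was -0.04 and 48.1% of calls were higher, against 34.9% (30 higher, 56 lower) when scaled to library totals alone, where the median was -1.18, and 54.5% (48 higher, 40 lower) with median-of-ratios factors, where it was 0.78. The balance of higher and lower families therefore depends on the scaling. Of the 39 higher, 33 kept their direction under all scalings, and 40 of the 42 lower did; miR156, miR157, miR159, miR161, miR447, miR1886, miR162 and miR822 did not. Depth limits the higher families: 14 were listed in all total libraries, and 12 were at 0 in all 9, such as miR869, miR844, miR833 and miR397. With libraries thinned to the same total of miRNA reads, 16 of 63 families passed as higher and 37 as lower, of which 16 and 33 were among the calls above. miR847 (5.83), miR781, miR400 and miR839 were higher with some total libraries at 0. miR8175, miR5139, miR8155 and miR6173 were listed at 0 in AGO1 libraries, and miR6478 was lower (-5.31). Total and AGO1 libraries also differ in their preparation, which this contrast cannot separate from binding.

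No list passed in this contrast: auxin (1 higher, 3 lower of 5), copper (2 and 1 of 3), defence (4 and 2 of 10), triggers (2 and 2 of 7), phosphate (0 and 2 of 3), secondary metabolism (2 and 0 of 3) and partners of other ARGONAUTE proteins (2 and 1 of 3, the 2 being miR165 and miR166, which share sequences; median 2.27, mean -0.96) each had an adjusted p of 0.517 to 0.721, and development had 5 and 5 of 10 and silencing 1 and 2 of 4 (adjusted p = 0.712 each). Of the lists too small for a set test, other organs had 2 and 0 of 2 and sulfate and nitrogen 0 and 2 of 2. Within treatments, 36 families were higher and 33 lower in untreated leaves, 31 and 34 in mock and 28 and 36 in Alternaria, and after thinning 13 and 31, 12 and 30, and 12 and 30. When scaled to library totals alone the numbers were 26 and 43, 21 and 43, and 19 and 50, and with median-of-ratios factors 42 and 30, 45 and 32, and 38 and 32. In each treatment miR164 (-9.06, -10.06 and -10.14) and miR390 (-8.24, -8.28 and -7.95) were lower in AGO1. The interaction, the change with Alternaria relative to mock in AGO1-bound against total libraries, passed for none of 95 families. This held by limma and limma-voom (7 and 8 at an unadjusted p under 0.05). The simulations did not cover the interaction, so how often it misses a difference is unknown. Without mock total replicate 3, limma called 1 family higher and 5 lower.

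In a contrast that also holds the difference in library preparation, sequences that begin with U lay higher in AGO1-bound over total libraries than others. Their mean log2 of AGO1-bound over total was 0.78 (SD 2.95, 223 sequences), against -2.53 (SD 3.77, 156 sequences) for the rest, a difference of 3.31 (permutation p = 1e-05, the smallest the resampling can give). Means were -3.36 for A, -3.54 for G and -0.43 for C. U-initial sequences made up 99.8% of miRNA reads in AGO1 and 78.2% in total libraries, and A-initial ones 0.0427% and 16.3%. Sequences 21 nt long did not differ from other lengths by more than their spread (difference -0.45, permutation p = 0.253; 148 and 231 sequences). Sequences of 1 family are not independent.

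**Figure D3:**
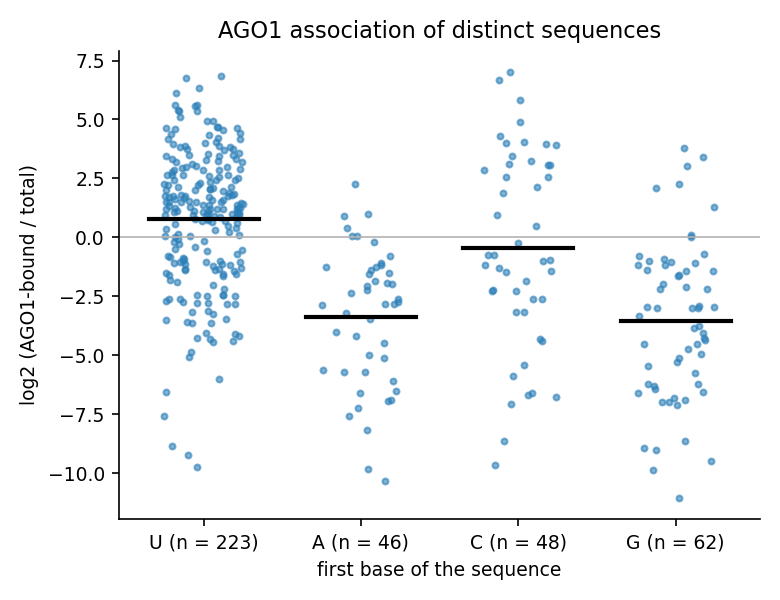
log2 of AGO1-bound over total small RNA (mean of 3 treatments) of 379 distinct sequences, by first base. Points are sequences and lines are means: 0.78 for U, -3.36 for A, -0.43 for C and -3.54 for G.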

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

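The interaction tested here was chosen before the data were examined, and reading it for distinct sequences rather than families was chosen after the family result was seen. Of 379 distinct sequences tested, 6 had a change with Alternaria relative to mock that differed between AGO1-bound and total libraries by limma, 3 in each direction. In total libraries 2 of them, from the 3p strand of miR169 hairpins, fell: GCAAGTTGACCTTGGCTCTG by a log2 of -4.09 (interaction 3.76 ± 0.76, adjusted p = 0.0150) and GCAAGTTGACCTTGGCTCTGT by -2.51 (2.51 ± 0.37, adjusted p = 0.000835). The others were 3 sequences of miR399, GGGCGAATACTCCTATGGCAGA (-3.11), TGCCAAAGGAGAGTTGCCC (-3.49) and TGCCAAAGGAGATTTGCCCGG (-2.73), and GGACAGTCTCAGGTAGAC of miR5368 (4.36), a plastid 23S rRNA fragment. All 6 were listed at 0 in all 6 mock and Alternaria AGO1 libraries, so the interaction rests on their values in total libraries and holds no measured change in AGO1. In total libraries alone, only the 2 miR169 sequences passed limma (adjusted p = 0.0193 and 0.000216). The first and second miR399 sequences (adjusted p = 0.0941 and 0.0907) and that of miR5368 (0.0521) did not. The third miR399 sequence had no value there. No biological explanation was tested.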

How the results depend on the processing

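Tests chosen only after the results were seen are limma-voom, pseudocounts of 10 and 25 CPM, single runs, zeros at the hidden count, removal of families without a MIR transcript, genome-matched scaling, the fit without untreated total replicate 3 in Alternaria against mock, thinning, and leaving out replicates for the lists and for base and length. The planned DESeq2 Wald test was not run. For 89 named changes past the threshold, 1851 of 2059 values under an alternative kept direction and threshold, 205 kept direction alone and 3 reversed. These numbers pool treatment changes with differences between AGO1-bound and total libraries, which reach a log2 of -12.1 (miR8175, mean of 3 treatments). They therefore do not describe the treatment calls alone, which are given by comparison below. The limits are the depth of total libraries, the listing minimum and 3 replicates. Unless a setting's own construction shows it (fewer families or libraries), the cause was not tested.

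For Alternaria against mock, 5 families passed in total libraries and 3 (1 higher, 2 lower) with median-of-ratios factors, library totals, a mean of at least 100 reads, removal of families without a MIR transcript or thinning, and 2 with zeros at the hidden count or genome-matched scaling. In AGO1 libraries 4 passed, against 2 with library totals and 0 in the fit of all 18. For mock against untreated total libraries, 4 passed, against 2 with a mean of at least 100 reads, 11 (5 higher) in the fit of all 18, 7 (2 higher) with zeros at the hidden count, 1 without families that lack a MIR transcript and 48 with genome-matched scaling (47 higher and 1 lower in mock). For Alternaria against untreated, 19 passed in total libraries and 61 with genome-matched scaling. In AGO1 libraries 7 passed, against 12 with a mean of at least 100 reads, 1 in the fit of all 18, 2 with zeros at the hidden count and 3 with thinning. AGO1-bound against total gave 81, against 51 with a mean of at least 100 reads and 53 with thinning, and thinning gave 44 in untreated, 42 in mock and 42 in Alternaria leaves (69, 65 and 64 otherwise). The interaction gave 0, against 1 with library totals and 2 with run 2 only.

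With the replicate number as a block, 2 families passed for Alternaria against mock in total libraries, 7 in AGO1 libraries and 11 for Alternaria against untreated in AGO1 libraries; the response of miR169 in AGO1 stayed at -0.52 without passing fry, and 1 of 2 lists passed. With an estimated correlation 0 lists passed.

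Reversed values were miR838 (-0.18, Alternaria against untreated, total) and miR845 (-0.16, Alternaria against mock, AGO1) with zeros at the hidden count; miR5139 (0.32), miR390 (1.12) and miR170 (1.07) for Alternaria against untreated and miR169 (0.38) for mock against untreated in total libraries with genome-matched scaling; and miR159 for Alternaria against untreated in total libraries, -0.00098 to 0.65 with 1 replicate left out and negative without untreated replicate 2. Of these miR838, miR5139 and miR169 had passed the test.

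Leaving out 1 replicate at a time gave 2 to 6 families for Alternaria against mock in total libraries (3 without mock 1, mock 2 or Alternaria 2, and 2 without Alternaria 1 or 3), 10 to 25 for Alternaria against untreated (10 without Alternaria 3) and 0 to 8 for mock against untreated (8, 1 and 0 without untreated 1, 2 and 3, and 2 without mock 3; higher families were 4 without untreated 1, 1 without mock 2 and 1 without mock 3). AGO1 libraries gave 2 to 3 for Alternaria against mock (2 without mock 1 or 2 or Alternaria 2 or 3), 0 to 14 for Alternaria against untreated (14 without untreated 3, 0 without Alternaria 2) and 0 to 1 for mock against untreated (1 without untreated 3). AGO1-bound against total gave 74 to 85, and 64 to 70 in untreated, 59 to 64 in mock and 58 to 63 in Alternaria leaves. The interaction gave 0 to 6 (6 without mock total 3). The difference by first base was 2.99 to 3.16 and by length -0.47 to -0.37; the response in AGO1 was 0.68 to 0.82 for the higher set and -0.72 to -0.45 for miR169 (past the threshold without Alternaria 1 alone). Lists passing numbered 0 to 4 (0 without untreated total 1 or mock total 3, 1 without untreated total 2 or 3 or Alternaria total 2, and 4 without untreated AGO1 1).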

Other observations

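Tests of the first base as a cause of the AGO1 profile and the counts of other splits were chosen before the data were examined; the tests on miR163, on rRNA and tRNA fragments, on library preparation, on miR169 strands and on hairpins were chosen only after the results were seen.

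In families with reads from both strands, the strand that begins with U mostly had the higher log2 of AGO1-bound over total. Where 1 strand began with U and the other did not, this held in 20 of 23 families, with 3 the other way. The mean difference was 4.22 (SD 5.06, permutation p = 0.00069). In some families, such as miR160, miR167 and miR168, both strands were lower in AGO1, and the U strand was only less depleted. A family can pool several hairpins, miR165 and miR166 share sequences, and library preparation also differs in this contrast. In 31 families the strand less abundant in total libraries differed from the other by -1.50 on average (SD 5.61, permutation p = 0.147, lower in 19 and higher in 12). That strand was picked from the same total libraries that the ratio is taken over. The test therefore cannot decide whether abundance separates the strands. For miR169, the change after Alternaria lay in the 3p strand, with a log2 of -1.62 in total libraries (adjusted p = 0.00271 by limma), while the 5p strand had a log2 of -0.57 in AGO1 libraries, too small against its spread to tell whether it fell alongside.

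The difference between AGO1-bound and total profiles may in part be sorting by first base, since U-initial sequences differed from others by 3.31. Of the other 99 of 100 splits of libraries 0 reached that value (highest 2.57), but splits of libraries do not test first base among sequences. A different library preparation may also contribute and cannot be told apart from binding, because each library type was prepared in its own way. Sequences with the same first 18 bases, for which a ligation bias at the start of the molecule would be alike, had an SD of 2.34 among 222 sequences, against 3.69 over all sequences. This SD cannot decide on preparation, because such sequences differ at their other end. The listing minimum can also hide them in the shallower total libraries.

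miR163 was listed at 0 in untreated total replicate 3. Low depth was excluded, since 1186 reads were expected from the share in replicates 1 and 2 and at most 28 of each of its 12 listed sequences can be hidden. The fewest miR163 reads in the other 17 libraries were 1021. This cannot tell whether that library was exchanged with another of the series, because an exchange would only move the 0 to another label. A loss of the longest sequences in that library may be a cause: the 6 other 23-nt sequences stood at 0.412 of their level in replicates 1 and 2, and 18-nt and 19-nt sequences at 3.05 and 3.35. Against it, the 36 sequences of 22 nt were not reduced (1.14; 20 nt 1.18, 21 nt 0.934), and no other 24-nt sequence had reads there to decide it. A biological cause was not tested.

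Plastid rRNA fragments were lower in mock and Alternaria than in untreated total libraries. Per 1000000 genome-matched reads they were listed at 0.336 of the untreated level, with the lowest untreated library (20.7) above the highest other (17.7). These listed values cannot exclude a larger miRNA share alone, because of the listing minimum. Each of the 17 sequences can hide up to 28 reads per library, and mock and Alternaria libraries listed 118 to 472 reads of the class. The untreated mean was also raised by replicate 3 (47.6, against 21.5 and 20.7 in replicates 1 and 2). Mock was listed at 0.410, which for the same reasons cannot exclude Alternaria as the whole cause. tRNA fragments, at 0.939, are consistent with a larger miRNA share alone. Whether the treatment itself or RNA handling lowered the rRNA fragments was not tested.

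Other splits of the same libraries were counted. With 3 against 3 there are 10 splits, too few for a share under 0.05. In total libraries 1 split gave as many families for Alternaria against mock (real 5, highest other 1), Alternaria against untreated (19 and 0) and mock against untreated (4 and 3). In AGO1 libraries the real and highest other numbers were 4 and 0, 7 and 0, and 0 and 3, and for AGO1-bound against total 69 and 0 in untreated, 65 and 0 in mock and 64 and 0 in Alternaria leaves; 1 split gave as many in each, but 10 for mock against untreated. For the mean of treatments 1 of 100 splits gave as many (81, highest other 69, which points to a structure of the libraries that other splits share in part). For first base it was also 1 of 100. Any other split mixes AGO1 with total libraries, which differ in depth and preparation. These counts show that library type matters, but cannot separate binding from preparation or the listing minimum. For length, 1 of 100 splits of libraries gave as large a difference (0.445 in size, highest other 0.353), under the same limit. Among sequences the difference lay within their spread (permutation p = 0.253), so it was left open. For the interaction 100 of 100 splits gave as many as the real 0 (highest other 6). For the phosphate list 2 of 10 splits gave a camera p as small for Alternaria against mock (real 0.00286, smallest other 8.81e-05) and 1 of 10 for Alternaria against untreated (0.00244 and 0.0207). For the response in AGO1, 1 of 10 splits gave a fry p of limma as small for the higher set (4.57e-05 and 0.171) and for miR169 (0.0433 and 0.0803).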
